A study of Mus musculus with 23 samples.

How the data were processed

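The series holds 23 RNA-seq libraries of mouse brain in 4 groups of genotype and treatment, prepared with a stranded mRNA kit per the labels' protocols. The authors deposited one table of 18848 genes by 23 libraries with decimal, never negative values, a signal made of read counts scaled between libraries. The submitters' processing notes name Salmon 1.1.0, R 3.6.2, DESeq2 1.26.0 and the build GRCm38, with no role or order. The annotation release, the filter on low genes and the import settings are not given in the sources used here. The lowest gene mean in the table was 3.58. Low values in each library cluster near multiples of one step, from 0.877 to 1.285, the worth of 1 read after scaling. Between 56.6% and 78.3% of values up to 5 steps lay within 0.15 of a whole multiple, so whole reads could not be recovered. Dividing each library's total by its step gave an estimated depth of 25.5 M to 37.4 M reads. Scaling makes totals alike, so differences in total RNA cannot be seen, and genes that share sequence with pseudogenes can exchange reads.

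The design written before the data were examined named a count test, with limma in its place if the table held normalised values. The table did, so limma 3.58.1 in R 4.3.3 was used on log2(value + 1), with 1 coefficient per group over all 23 libraries, empirical Bayes moderation with a mean trend and robust settings, and Benjamini-Hochberg adjustment at 0.05 over the 17256 genes with a mean of at least 10. A fold change on this scale understates the change of low genes. Tests are two-sided. The count-based alternatives of the plan, including DESeq2, which the submitters' processing notes name, do not apply to such values. Gene symbols came from a table of gene identifiers, with 16 identifiers left without one, and coordinates from GENCODE M21 on GRCm38. No column of the table lacked a sample. The fifth WT DCS library in the titles carries the number 6 in its description, so the replicate block was run with either numbering.

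The 6 contrasts tested were genotype under each treatment, treatment in each genotype, their interaction, and treated HT against untreated WT. Gene lists were fixed before the data were examined, covering synaptic and metabolic pathways, stress and signalling programmes, cell types and brain regions. Of these, 44 were fixed and 43 with at least 5 measured genes tested, the sex chromosome list serving only as a label check. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation, fry of limma, and a permutation test of list means over libraries (exact for 2 groups, 100000 resamples for the interaction) were alternatives, the last chosen after seeing the data. So was an exact permutation within replicate numbers 1 to 3 and 4 to 6. The named genes are the NMDA receptor subunits, the genes past the threshold with the largest changes, up to 4 members of each list described and, where fewer than 4 genes passed in a direction, the 3 with the smallest p in it, leaving out predicted gene models. Sex markers were named as a check. Some genes that the rule names are not reported here. The limits to the 6 called lists with the smallest p and to 2 members of each were set after the data were seen. Beyond that limit, the meningeal and choroid plexus lists (HT vehicle against WT vehicle) and the cerebellar and microglia lists (HT DCS against WT DCS) were added later, for the tissue they mark. The hindbrain list is described as well, although camera called it in no contrast.

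For the correlation between the genotype effect and the DCS effect in HT, group labels were permuted 100 times over the 18 libraries concerned. This null replaced 2 others after their output was seen: permuted residuals, in which a draw that reassembles a real group has a mean of exactly 0 and can give an r fixed by construction, and Gaussian noise with the residual covariance, which widens the spread. Their mean r was -0.49 and -0.47, against -0.50 for the null used.

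The tests were tested on simulated counts with the means and spread of the real genes, drawn independently between genes, among 17256 genes per contrast, of which 67 were changed by 0.25 on the log2 scale, 67 by 0.5 and 66 by 1. For HT vehicle against WT vehicle, limma recovered 56.7%, 73.1% and 87.9% of them in that order. For the interaction it recovered 17.9%, 62.7% and 80.3%. Camera called a list of 24 genes shifted by -0.20 in each contrast and 0 of the 42 other lists. Genes vary together in the real libraries, which the simulation leaves out. Each library was counted once. Whether any of them share a mouse is not given, and no test here can tell.

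Other alternatives were limma without a trend, quantile normalisation, no filter or a mean of at least 50, pseudocounts of 0.5 and 5, only the groups compared, the replicate number as a block, the first principal component of the residuals, array weights, and leaving out each library in turn. The list mean differences were also recomputed without each library. Chosen after seeing the data were the first 2 principal components, the replicate numbers in 2 blocks (1 to 3 and 4 to 6), the hindbrain list mean as a covariate, and leaving out together WT vehicle replicate 2, WT DCS replicate 2 and HT DCS replicate 5, which stand apart on the first principal component.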

Results

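Polyadenylated RNA was sequenced from brain of male C57BL/6J mice at postnatal day 17, wild-type (WT) or heterozygous (HT) for the Grin2b C456Y mutation. Grin2b encodes the GluN2B subunit of the NMDA receptor, a glutamate-gated ion channel. Mice of each genotype received vehicle or DCS. DCS is the usual abbreviation of D-cycloserine, a partial agonist at the glycine site of NMDA receptors; the labels give the abbreviation alone. There were 6 WT vehicle, 5 WT DCS, 6 HT vehicle and 6 HT DCS libraries. The labels name brain with no region. They do not state that each library came from its own mouse, so p-values measure the spread between these samples, which may be technical. Normalised read counts summed to between 32.3 M and 33.5 M per library. The spacing of the low values put the depth before scaling at about 25.5 M reads in HT DCS replicate 5 and 37.4 M in WT vehicle replicate 4, the lowest and highest of the 23 libraries. Of 18848 genes, 17256 with a mean of at least 10 were tested.

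The NMDA receptor subunit mRNAs were measured at similar levels in the 4 groups. Grin2b (ENSMUSG00000030209, GRCm38 chromosome 6, 135713233 to 136173511, minus strand, protein coding) had a normalised read count of 17910 ± 1190 (SD, n = 6) in WT vehicle, 18770 ± 2540 (n = 5) in WT DCS, 18270 ± 1880 (n = 6) in HT vehicle and 18950 ± 1880 (n = 6) in HT DCS. The log2 difference of HT vehicle from WT vehicle was 0.02, with a 95% interval from -0.15 to 0.20 (limma, adjusted p = 0.999). The table measures the summed transcripts of both alleles, so it does not check which allele a library carried. Grin1, which encodes the obligatory GluN1 subunit, had means of 21030 in WT vehicle and 20590 in HT vehicle. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in every group, at means of 1802, 1300, 975 and 516.6 in WT vehicle, and the mice are labelled male.

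**Figure D1:**
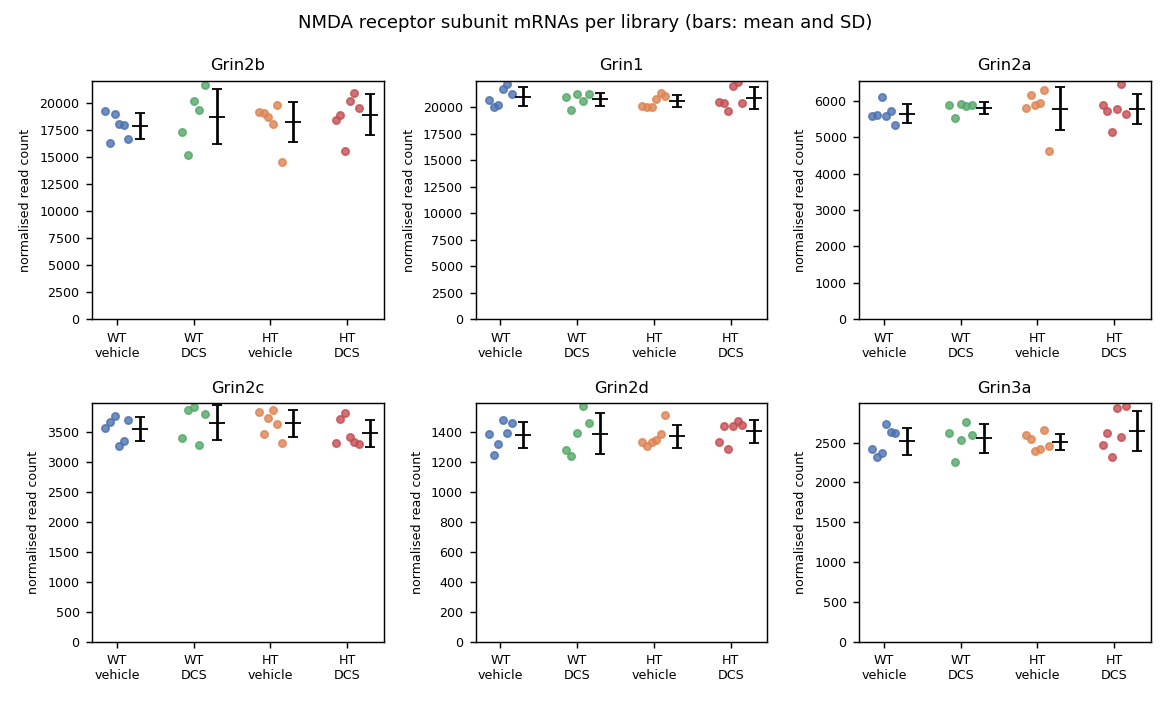
Normalised read counts of 6 NMDA receptor subunit mRNAs (y axis, from 0) in each library (points) of the 4 groups (x axis), with bars for the mean and SD. Grin2b means lie between 17910 in WT vehicle and 18950 in HT DCS. HT vehicle replicate 6 is the lowest Grin2b library of its group at 14620.

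The first comparison asked how the heterozygous brain differs without DCS. Striatal markers lay lower in HT vehicle than in WT vehicle: 13 of the 16 measured genes had a lower mean, the list mean differed by -0.10 ± 0.05 (SE, log2), and 6 of 6 HT vehicle libraries lay under the WT vehicle mean (limma camera, adjusted p = 1.75e-06; adjusted p = 0.49 with an estimated correlation). Adora2a, an adenosine receptor gene of striatopallidal neurons, had 955.5 normalised reads in HT vehicle and 1207 in WT vehicle, and Syndig1l had 1066 and 1214. Oligodendrocyte and myelin markers were lower in 23 of 24 genes, by -0.09 ± 0.08 (limma camera, adjusted p = 3.05e-05; adjusted p = 0.67 with an estimated correlation), with Bcas1 at 5903 against 6295 and Tmem125 at 505 against 575.2. Hindbrain and monoamine markers averaged 6.72 (log2) in HT vehicle and 6.95 in WT vehicle, lower in 4 of 6 HT vehicle libraries. This list was not called here or in any other contrast (limma camera). Pericyte and smooth muscle markers were higher in 11 of 13 genes, by 0.13 ± 0.07 (limma camera, adjusted p = 8.17e-05; adjusted p = 0.49 with an estimated correlation), among them Pdgfrb, the receptor that marks pericytes, at 915.6 against 809.6, and Cspg4 at 1023 against 915.8. Of the lists for the borders of the brain, meningeal fibroblast markers were higher in 12 of 15, by 0.10 ± 0.08, and choroid plexus markers in 11 of 15, by 0.16 ± 0.11 (limma camera, adjusted p = 0.0121 and 0.00471; adjusted p = 0.67 and 0.63 with an estimated correlation), each in 4 of 6 HT vehicle libraries. The meningeal difference was 0.04 without WT vehicle replicate 3 (limma camera, adjusted p = 0.5), and its call was lost without HT vehicle replicate 3 (adjusted p = 0.054) or 6 (adjusted p = 0.088). The choroid plexus difference was 0.10 without HT vehicle replicate 3 (limma camera, adjusted p = 0.12). Activity-induced early genes, the transcripts that follow neuronal firing, were higher in 36 of 43 genes, by 0.11 ± 0.13 (limma camera, adjusted p = 1.91e-04; adjusted p = 0.67 with an estimated correlation), with Plk2 at 4332 against 4062 and Pcsk1 at 1298 against 1203. Microglia markers averaged 7.98 (log2) in HT vehicle and 7.83 in WT vehicle. Interferon and antigen presentation genes were lower in 20 of 21, by -0.20 ± 0.12 (limma camera, adjusted p = 2.06e-04; adjusted p = 0.49 with an estimated correlation), with Irf9 at 342 against 386.9 and Rsad2 at 24.78 against 35.44. Mitochondrially encoded mRNAs were lower in 11 of 13, by -0.08 ± 0.06 (limma camera, adjusted p = 8.17e-05; adjusted p = 0.49 with an estimated correlation), with mt-Nd1 at 134600 against 144900 and mt-Cytb at 199300 against 215600. The list mean lay on the stated side of the WT vehicle mean in 5 of 6 HT vehicle libraries for the myelin, pericyte, interferon and mitochondrial lists and in 4 of 6 for the early genes. Without WT vehicle replicate 1 the striatal difference was -0.06 (limma camera, adjusted p = 0.0011). Without HT vehicle replicate 6 the myelin difference was -0.04 and its call was lost (limma camera, adjusted p = 0.051). The early gene difference was 0.03 without WT vehicle replicate 4, where its call was lost (limma camera, adjusted p = 0.089), 0.07 without HT vehicle replicate 3 or 6, and 0.18 without HT vehicle replicate 4. The interferon difference was -0.11 without WT vehicle replicate 3, and the mitochondrial one -0.05 without HT vehicle replicate 1. The mitochondrial list is uncertain, since mt-Co3 moved against its nuclear pseudogene Gm28437 across the 23 libraries, as deviations from the group means. Pearson r was -0.90 and Spearman rho -0.89 (permutation p = 1e-05 for each, adjusted 2e-05 over 2 relations). Without the 2 farthest libraries r was -0.89, and 1e-05 is the smallest p that these permutations can give. Of this list only mt-Co3 was compared with a nuclear copy, so mt-Nd1 and mt-Cytb were not checked. This pair and the Rps6 pair below were not in the plan, and the adjustment covers only these 2.

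No single gene passed the test between HT vehicle and WT vehicle (0 of 17256, limma; 729 at an unadjusted p under 0.05, where 863 are expected). The genes with the smallest p and a higher mean in HT vehicle were Ccn2, a matricellular protein gene (966.9 against 793.2, log2 difference 0.29 ± 0.06 SE, limma adjusted p = 0.536), Krt18 (19.52 against 10.68) and Ptk2, focal adhesion kinase (3584 against 3250). Those with a lower mean were St8sia3, a sialyltransferase (4731 against 5317), Col24a1 (298.4 against 453.6, log2 difference -0.61 ± 0.13 SE, limma adjusted p = 0.59) and Adora2a. Each of these 6 genes lay on its side of the WT vehicle mean in 6 of 6 HT vehicle libraries. Their choice by the smallest p among 17256 genes favours such agreement, so it is no separate support. Of the 43 lists, 16 were called with the preset correlation and 0 with an estimated one. Those not described above were the stress response, excitatory neuron, microglia, endothelial, hypothalamic and olfactory lists, higher, and the proteasome and inhibitory neuron lists, lower. All of these but the endothelial list lost their call without at least 1 library. Adjusted over the list alone, 3 striatal genes passed, and 0 did among the myelin, pericyte, early, interferon and mitochondrial genes. These lists were picked by their p in the same data, so such a pass is not independent support.

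The second comparison set the genotypes side by side under DCS. Oligodendrocyte and myelin markers stood lowest in HT DCS: all 24 measured genes had a lower mean than in WT DCS, by -0.20 ± 0.09 (SE, log2) on average, and 5 of 6 HT DCS libraries lay under the WT DCS mean (limma camera, adjusted p = 4.65e-15; adjusted p = 0.87 with an estimated correlation). Mag, myelin-associated glycoprotein, had 13360 normalised reads in HT DCS and 15700 in WT DCS. An exact permutation test of that list mean over the libraries, two-sided, gave p = 0.093, adjusted 0.78 over the 43 lists. Within replicate numbers 1 to 3 and 4 to 6, blocks chosen after seeing the data, the exact permutation p was 0.025, again adjusted 0.78, over 200 splits. Hindbrain and monoamine markers, which include Hox genes, averaged 6.59 ± 0.58 (SD, n = 6, log2) in HT DCS and 6.84 ± 0.13 (n = 5) in WT DCS, but only 2 of 6 HT DCS libraries lay under the WT DCS mean. These were replicates 5 and 6, at 5.76 and 5.97, and the difference was -0.08 without replicate 5 and -0.12 without replicate 6. The hindbrain list was not called. Cytosolic ribosomal protein genes were lower in 62 of 80, by -0.04 ± 0.03 (limma camera, adjusted p = 4.33e-04; adjusted p = 0.87 with an estimated correlation), with Rps18 at 3212 against 3392. Nuclear genes of oxidative phosphorylation were lower in 63 of 74, by -0.04 ± 0.03 (limma camera, adjusted p = 7.68e-04; adjusted p = 0.87 with an estimated correlation), with Atp5e at 1332 against 1521 and Atp5j at 3120 against 3295. Striatal markers were lower in 12 of 16, by -0.07 ± 0.05 (limma camera, adjusted p = 0.00371; adjusted p = 0.87 with an estimated correlation), with Rasd2 at 2301 against 2616 and the dopamine receptor gene Drd2 at 597.9 against 691.8. Immature neuron markers were higher in 15 of 16, by 0.08 ± 0.08 (limma camera, adjusted p = 0.00946; adjusted p = 0.87 with an estimated correlation), with the growth cone gene Gap43 at 8658 against 7956 and Neurod1, the exception, at 2914 against 3148. Endothelial markers were higher in 14 of 18, by 0.07 ± 0.04 (limma camera, adjusted p = 0.00946; adjusted p = 0.87 with an estimated correlation), with Flt1 at 1456 against 1327 and Ly6c1 at 645.9 against 571.6. The list mean lay on the stated side in 6 of 6 HT DCS libraries for the striatal list, 5 of 6 for the endothelial, 4 of 6 for the ribosomal and immature neuron lists and 3 of 6 for oxidative phosphorylation. Cerebellar markers were lower in 15 of 19, by -0.06 ± 0.05, in 3 of 6 libraries, and microglia markers higher in 19 of 20, by 0.14 ± 0.18, in 4 of 6 (limma camera, adjusted p = 0.0105 and 0.018; adjusted p = 0.87 for each with an estimated correlation). The cerebellar difference was -0.003 without HT DCS replicate 5 (limma camera, adjusted p = 0.68), and its call was also lost without WT DCS replicate 1 (adjusted p = 0.071) or 4 (adjusted p = 0.073). The microglia difference was 0.29 without WT DCS replicate 2. It was 0.05 without WT DCS replicate 4 (limma camera, adjusted p = 0.54), 0.09 without HT DCS replicate 3 (adjusted p = 0.23) and 0.08 without HT DCS replicate 5 (adjusted p = 0.22), and its call was lost without WT DCS replicate 1 or 5 or HT DCS replicate 6 too (adjusted p = 0.091, 0.074 and 0.053). The myelin call held without any 1 library, and each of the other 5 lists described first was lost without at least 1 (limma camera). The ribosomal difference was -0.02 without HT DCS replicate 5 (adjusted p = 0.23), and its call was also lost without WT DCS replicate 1 (adjusted p = 0.071). That of oxidative phosphorylation was -0.01 without HT DCS replicate 5 (adjusted p = 0.19) or WT DCS replicate 1 (adjusted p = 0.26) and -0.02 without HT DCS replicate 6 (adjusted p = 0.053). The striatal difference was -0.04 without WT DCS replicate 1 (adjusted p = 0.071). The immature neuron difference was 0.04 without WT DCS replicate 2 (adjusted p = 0.18), 0.03 without HT DCS replicate 6 (adjusted p = 0.2) and 0.14 without WT DCS replicate 4, and the call was lost without WT DCS replicate 3 (adjusted p = 0.089). The endothelial call was lost without WT DCS replicate 3 (adjusted p = 0.058), HT DCS replicate 2 (adjusted p = 0.059) or HT DCS replicate 6 (adjusted p = 0.052).

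No gene passed between HT DCS and WT DCS (0 of 17256, limma; 1302 at an unadjusted p under 0.05). Col6a1, a collagen VI chain, had 2590 normalised reads in HT DCS and 2254 in WT DCS (log2 difference 0.20 ± 0.04 SE, limma adjusted p = 0.225), Nrn1l 13.06 and 5.19, and Shkbp1 527.5 and 435.2. Syt2, the fast calcium sensor of transmitter release in hindbrain and interneuron terminals, had 4448 and 5599 (log2 difference -0.34 ± 0.07 SE, limma adjusted p = 0.225), Hpca, the neuronal calcium sensor hippocalcin, 10240 and 11400, and Smad7 733.6 and 870.9. Each lay on its side of the WT DCS mean in 6 of 6 HT DCS libraries, which their choice by smallest p favours also under chance. Among the HT DCS libraries Syt2 was lowest in replicates 5 and 6 (3967 and 4014), those with the low hindbrain means. The other HT DCS libraries, at 4453 to 5082, lay under the WT DCS mean too. Whether less hindbrain tissue accounts for part of the Syt2 difference was not tested. Of the 43 lists, 14 were called with the preset correlation and 0 with an estimated one. Those not described above were the autism genes, higher, and the voltage-gated channel, stress response, heat shock, cholesterol and glycolysis lists, lower. Each of these lost its call without at least 1 library. Adjusted over the list alone, 3 myelin genes and 4 striatal genes passed, and 0 did in the ribosomal, oxidative phosphorylation, immature neuron and endothelial lists. The lists were chosen by their p in this contrast, so these passes do not count as separate evidence. Syt2 alone passed when HT vehicle replicate 6, which is in neither group and enters only the estimate of spread, was left out (limma, adjusted p = 0.0215). With the first 2 principal components of the residuals as covariates, an alternative chosen after seeing the data, 40 genes passed, 8 higher and 32 lower, Syt2, Mag and Cnp among the lower. These components describe deviations within groups, so they leave the fold changes as they are and take out only spread. More calls are built into that setting, and the 40 genes are no further evidence.

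**Figure D2:**
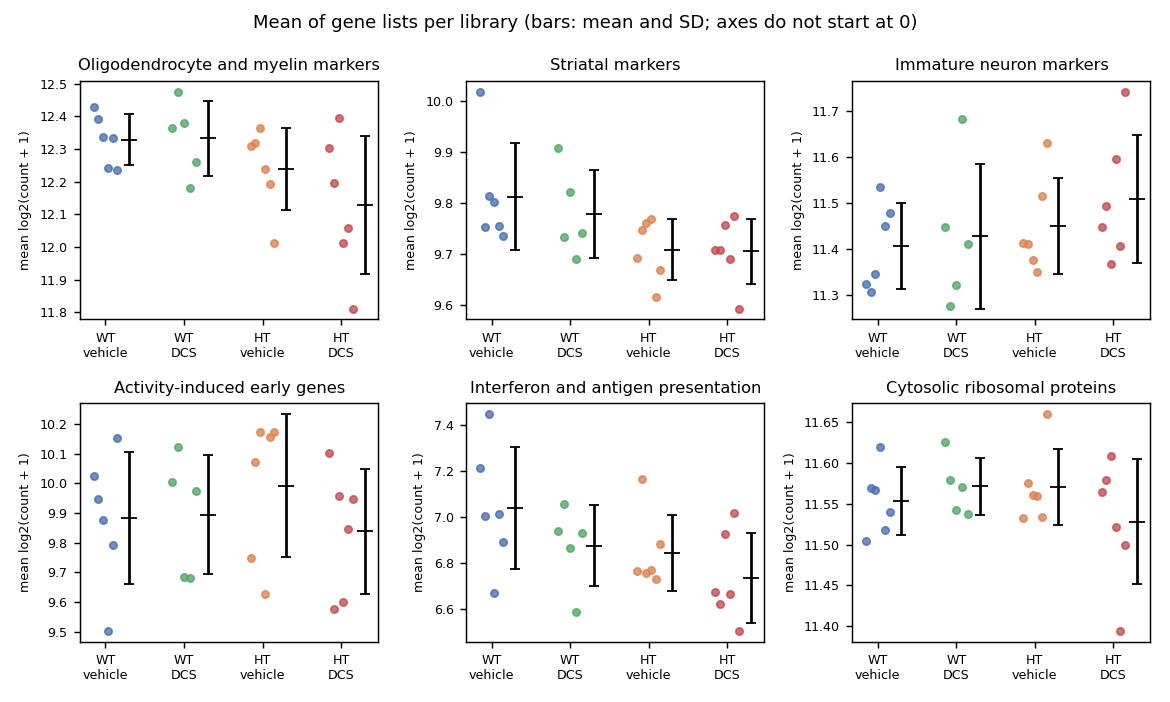
Mean log2(normalised read count + 1) over the genes of 6 lists (y axis, not starting at 0) in each library (points) of the 4 groups (x axis), with bars for the mean and SD. The oligodendrocyte and myelin mean is 12.33 in WT DCS and 12.13 in HT DCS, and the spread of the HT DCS libraries, an SD of 0.21, is as large as that difference.

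DCS in WT mice was compared with vehicle to ask what the treatment alone does. Genes of the interferon and antigen presentation list were lower under DCS in 19 of 21, by -0.16 ± 0.13 (SE, log2), with Irf7, a transcription factor of the interferon response, at 40.95 normalised reads against 57.35 and Stat2 at 1170 against 1271 (limma camera, adjusted p = 0.00141; adjusted p = 0.90 with an estimated correlation). Choroid plexus markers were higher in 13 of 15, by 0.17 ± 0.12, with Folr1 at 75.4 against 51.91 and Kcne2 at 37.98 against 27.03, and meningeal fibroblast markers in 14 of 15, by 0.10 ± 0.08, with Col1a2 at 1216 against 1048 and Igfbp2 at 1038 against 930.8 (limma camera, adjusted p = 0.0165 for each; adjusted p = 0.90 for each with an estimated correlation). Cholesterol synthesis genes were higher in 16 of 23, by 0.04 ± 0.02, with Ebp at 744.2 against 627.6 and Dhcr7 at 1710 against 1577 (limma camera, adjusted p = 0.0165; adjusted p = 0.90 with an estimated correlation). Proliferating progenitor markers were higher in 16 of 19, by 0.15 ± 0.12, with Mcm3 at 77.4 against 59.45 and Aurkb at 24.63 against 19.04 (limma camera, adjusted p = 0.02; adjusted p = 0.90 with an estimated correlation). Olfactory bulb markers were higher in 9 of 12, by 0.08 ± 0.04, with Cdhr1 at 1237 against 1092 and Doc2g at 684.5 against 597 (limma camera, adjusted p = 0.0266; adjusted p = 0.90 with an estimated correlation). The list mean lay on the stated side in 5 of 5 WT DCS libraries for the cholesterol and olfactory lists, 4 of 5 for the interferon and progenitor lists and 3 of 5 for the choroid plexus and meningeal lists. Each of these 6 calls was lost without at least 1 library (limma camera). The choroid plexus difference was 0.06 without WT DCS replicate 2 (adjusted p = 0.36), the library in which Kcne2 stood at 68.69 against 26.24 to 37.31 in the others of its group. The meningeal difference was 0.06 without that library (adjusted p = 0.25) and 0.04 without WT vehicle replicate 3 (adjusted p = 0.47). The interferon difference was -0.08 without WT vehicle replicate 3 (adjusted p = 0.11) and -0.09 without WT DCS replicate 4 (adjusted p = 0.13). The progenitor difference was 0.10 without WT DCS replicate 4 (adjusted p = 0.2), and its call was also lost without WT DCS replicate 2 (adjusted p = 0.12) or WT vehicle replicate 1, 5 or 6 (adjusted p = 0.076, 0.076 and 0.057). The cholesterol call was lost without WT vehicle replicate 6 (adjusted p = 0.059), and the olfactory call without that library (adjusted p = 0.059), WT vehicle replicate 2 (adjusted p = 0.091) or WT DCS replicate 4 (adjusted p = 0.16). The interferon, choroid plexus, meningeal and olfactory lists were called in the same direction between HT vehicle and WT vehicle. For each, WT vehicle had the most extreme group mean. The interferon mean was 7.039 there, against 6.875 in WT DCS, 6.844 in HT vehicle and 6.734 in HT DCS. Both comparisons use the same WT vehicle libraries, so they are not independent. The interaction and HT DCS against WT vehicle use them too.

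No gene passed between WT DCS and WT vehicle (0 of 17256, limma; 497 at an unadjusted p under 0.05). The smallest p values with a higher mean under DCS were those of Adamtsl2 (331.2 against 259.3, log2 difference 0.36 ± 0.09 SE, limma adjusted p = 1), Shisal2b (21.37 against 7.68) and Krt18 (19.2 against 10.68). With a lower mean they were those of Nrn1l (5.19 against 12.95, log2 difference -1.21 ± 0.25 SE, limma adjusted p = 0.888), Mapre1, a microtubule plus-end protein gene (3985 against 4711), and Gckr (18.97 against 37.85). All 5 WT DCS libraries lay on the stated side of the WT vehicle mean for each of these 6 genes. Genes picked by smallest p tend to show this also under chance. Krt18 was also named above as higher in HT vehicle, against the same WT vehicle libraries, so its differences are not independent. Nrn1l, also named between HT DCS and WT DCS, shares the WT DCS libraries in the same way. Grin2b differed by 0.06 ± 0.09 (SE, log2). Of the 43 lists, 7 were called with the preset correlation and 0 with an estimated one, and adjusted over the list alone 0 genes of the 6 lists described passed. The other list was that of the stress response, higher, and it lost its call without some libraries.

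DCS in HT mice was compared with vehicle to ask whether the treatment acts in the mutant. Ribosomal protein genes were lower under DCS in 63 of 80, by -0.04 ± 0.03 (SE, log2), with Rps6 at 3759 against 4331 and Rps18 at 3212 against 3485 (limma camera, adjusted p = 6.48e-06; adjusted p = 0.86 with an estimated correlation). Rps6 is uncertain, since it moved against its processed pseudogene Rps6-ps4 across the 23 libraries, as deviations from the group means (Pearson r = -0.76, permutation p = 4e-05, adjusted 4e-05 over 2 relations; Spearman rho = -0.72, permutation p = 1e-04, adjusted 1e-04; r = -0.76 without the 2 farthest libraries). Myelin markers were lower in 22 of 24, by -0.11 ± 0.08, with Mag at 13360 against 14930 (limma camera, adjusted p = 6.48e-06; adjusted p = 0.86 with an estimated correlation). Hindbrain markers averaged 6.59 (log2) in HT DCS and 6.72 in HT vehicle, lower in only 2 of 6 HT DCS libraries. Without HT DCS replicate 5 the direction turned, to a difference of 0.04. Without replicate 6 it was -0.001. The hindbrain list was not called. Activity-induced early genes were lower in 36 of 43, by -0.15 ± 0.13, with Jun at 1780 against 1950 and Rheb on the other side at 2509 against 2377 (limma camera, adjusted p = 3.58e-04; adjusted p = 0.86 with an estimated correlation). Oxidative phosphorylation genes were lower in 53 of 74, by -0.03 ± 0.03, with Atp5b at 34600 against 37000 (limma camera, adjusted p = 0.00249; adjusted p = 0.86 with an estimated correlation). Unfolded protein and integrated stress response genes were lower in 22 of 25, by -0.05 ± 0.03, with Ddit4 at 1674 against 1818 and Sdf2l1 at 239.3 against 276.4, and glucocorticoid-induced genes in 12 of 17, by -0.07 ± 0.05, with Tsc22d3 at 2032 against 2213 and Nfkbia at 488.6 against 542.5 (limma camera, adjusted p = 0.00844 and 0.00858; adjusted p = 0.86 for each with an estimated correlation). The list mean lay on the stated side in 5 of 6 HT DCS libraries for the early, stress response and glucocorticoid lists, 4 of 6 for the ribosomal and myelin lists and 3 of 6 for oxidative phosphorylation. Each of these 6 calls was lost without at least 1 library (limma camera). The myelin difference was -0.05 without HT DCS replicate 6 (adjusted p = 0.067). The ribosomal difference was -0.02 without HT DCS replicate 5 (adjusted p = 0.12) and -0.025 without HT vehicle replicate 6 (adjusted p = 0.16). That of oxidative phosphorylation was -0.008 without HT DCS replicate 5 (adjusted p = 0.45), -0.015 without HT vehicle replicate 6 (adjusted p = 0.43) and -0.016 without HT DCS replicate 6 (adjusted p = 0.23). The early gene call was lost without HT vehicle replicate 6 (adjusted p = 0.082), and the difference was -0.10 without HT DCS replicate 2. The stress response difference was -0.03 without HT DCS replicate 2 (adjusted p = 0.14), and its call was lost without HT vehicle replicate 6 (adjusted p = 0.091). The glucocorticoid difference was -0.04 without HT vehicle replicate 6 (adjusted p = 0.23) or HT DCS replicate 4 (adjusted p = 0.092), and its call was lost without HT DCS replicate 6 (adjusted p = 0.067).

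No gene passed between HT DCS and HT vehicle (0 of 17256, limma; 828 at an unadjusted p under 0.05). Ehd1, an endosomal recycling ATPase gene, had the smallest p, at 1867 normalised reads in HT DCS and 2325 in HT vehicle (log2 difference -0.32 ± 0.06 SE, limma adjusted p = 0.222). It passed without HT DCS replicate 4 (limma, adjusted p = 0.0164) and without HT vehicle replicate 1 (limma, adjusted p = 0.0479). Irak2 had 334.4 and 413.6, and the higher genes were Suco (1509 against 1250), Ccrl2 (32.96 against 18.89) and Col24a1 (432.9 against 298.4). Each of these 5 genes lay on its side of the HT vehicle mean in 6 of 6 HT DCS libraries, which their choice by smallest p favours also under chance. Col24a1 was also named above as lower in HT vehicle than in WT vehicle. Both of its differences use the same HT vehicle libraries, so they are not independent and do not show a reversal by DCS. Of the 43 lists, 8 were called with the preset correlation and 0 with an estimated one. The others were the immature neuron list, higher, and the cerebellar list, lower, and both lost their call without at least 1 library. Adjusted over the list alone, 3 ribosomal protein genes passed and 0 did in the other lists described. Since the lists were picked by their p in the same contrast, those passes are not independent support.

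The interaction asked whether the DCS effect differs between the genotypes, and 7 lists were called, each with a lower DCS effect in HT. Of 100 regroupings of the same libraries, the real one included, 82 called as many lists. Choroid plexus markers differed by -0.27 ± 0.17 (SE, log2), with Folr1 at -0.88 and Kcne2 at -0.77, and early genes by -0.17 ± 0.19 (limma camera, adjusted p = 0.0023 and 0.0018; adjusted p = 0.99 for each with an estimated correlation). Ribosomal protein genes differed by -0.06 ± 0.05, stress response genes by -0.08 ± 0.05, with the chaperone genes Hspa5 at -0.22 and Hyou1 at -0.15, and myelin markers by -0.12 ± 0.12 (limma camera, adjusted p = 7.69e-05, 8.75e-04 and 0.00213; adjusted p = 0.99 for each with an estimated correlation). Without WT DCS replicate 2 the choroid plexus difference was -0.16, that of early genes -0.11, and both calls and the myelin call were lost (limma camera, adjusted p = 0.066 for each). The early gene difference was -0.09 without WT vehicle replicate 4 (limma camera, adjusted p = 0.058), and the myelin difference -0.05 without HT DCS replicate 6 (limma camera, adjusted p = 0.26). The ribosomal difference was -0.03 without HT DCS replicate 5, its call was lost without HT vehicle replicate 6 (limma camera, adjusted p = 0.056), and the stress response difference was -0.05 without WT DCS replicate 1. No gene passed (0 of 17256, limma; 756 at an unadjusted p under 0.05), and adjusted over the list alone 0 genes of these lists passed. The smallest p values were those of Ehd1 (-0.38 ± 0.09 SE, limma adjusted p = 0.984), Scml2 (-1.85 ± 0.43 SE), Tmed9 (-0.20 ± 0.05 SE), Sike1 (0.55 ± 0.13 SE), Parp2 (0.36 ± 0.09 SE) and Gckr (1.28 ± 0.33 SE).

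HT DCS was set against WT vehicle to ask what remains different after treatment. Myelin markers were lower in all 24 genes, by -0.20 ± 0.08 (SE, log2), in 5 of 6 HT DCS libraries, with Mbp, myelin basic protein, at 199200 normalised reads against 235200 and Tspan2 at 9050 against 9923 (limma camera, adjusted p = 1.87e-16; adjusted p = 0.49 with an estimated correlation). Hindbrain markers averaged 6.59 (log2) in HT DCS and 6.95 in WT vehicle, lower in 4 of 6 HT DCS libraries. The difference was -0.19 without HT DCS replicate 5 and -0.23 without replicate 6. The hindbrain list was not called. Interferon genes were lower in 20 of 21, by -0.30 ± 0.12, in 6 of 6 libraries, with Irf7 at 36.31 against 57.35 (limma camera, adjusted p = 1.56e-07; adjusted p = 0.49 with an estimated correlation). Striatal markers were lower in 14 of 16, by -0.11 ± 0.05, in 6 of 6 libraries, with Adora2a at 962.7 against 1207 and Rasd2 at 2301 against 2613 (limma camera, adjusted p = 3.1e-06; adjusted p = 0.49 with an estimated correlation). Oxidative phosphorylation genes were lower in 62 of 74, by -0.04 ± 0.03, with Sdhc at 2536 against 2748 and Cox4i1 at 12120 against 12730 (limma camera, adjusted p = 8.57e-07; adjusted p = 0.77 with an estimated correlation). Immature neuron markers were higher in 15 of 16, by 0.10 ± 0.07, with Tubb2b at 8324 against 7448 and Nnat at 5953 against 5405, and high-confidence autism genes in 49 of 65, by 0.04 ± 0.02, with Wac at 3749 against 3423 and Tbr1 at 2408 against 2277 (limma camera, adjusted p = 1.42e-04 and 3.35e-04; adjusted p = 0.75 for each with an estimated correlation). The list mean lay on the stated side in 5 of 6 HT DCS libraries for the autism genes and 4 of 6 for the oxidative phosphorylation and immature neuron lists. The 6 calls described held without any 1 library (limma camera), and 4 differences moved by over 1.5 times. These were -0.02 for oxidative phosphorylation without HT DCS replicate 5, -0.07 for striatal markers without WT vehicle replicate 1, 0.06 for immature neuron markers without HT DCS replicate 6 and 0.05 for autism genes without HT DCS replicate 3. Of the 43 lists, 14 were called with the preset correlation and 0 with an estimated one. Those not described above were the AMPA and kainate receptor, excitatory neuron, microglia, pericyte, meningeal and progenitor lists, higher, and the ribosomal and proteasome lists, lower. All of these but the pericyte list lost their call without at least 1 library. Adjusted over the list alone, 13 myelin genes, 5 striatal genes and 2 interferon genes passed. The lists were picked by their p in the same data, so these passes are not independent support, and over all genes 0 passed.

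No gene passed over all genes between HT DCS and WT vehicle without a block (0 of 17256, limma; 1239 at an unadjusted p under 0.05). Syt2 had 4448 normalised reads in HT DCS and 5600 in WT vehicle (log2 difference -0.34 ± 0.06 SE, limma adjusted p = 0.262), Usp16 935.8 and 1172, and Lgi3 5002 and 5663. The Wnt co-receptor gene Lrp5 had 370.1 and 306.1, Cdhr1 1355 and 1092, and Zfp326 1001 and 827.9. Each lay on its side of the WT vehicle mean in 6 of 6 HT DCS libraries, as genes chosen by smallest p tend to do also under chance. With the replicate number as a block, an alternative planned before the data were seen, 11 genes passed, 1 higher and 10 lower (limma). Among them were Syt2 and Scn4b (adjusted p = 0.0104 for each), Usp16 (adjusted p = 0.0414), and Lgi3 and Adora2a (adjusted p = 0.0431 for each). With the number of the description labels as the block, only Scn4b (limma, adjusted p = 0.0204) and Syt2 (adjusted p = 0.0319) passed. Syt2 passed without HT vehicle replicate 6 (limma, adjusted p = 0.0103), and 22 genes passed with the first 2 principal components as covariates, chosen after seeing the data. Those components leave the fold changes as they are and take out only spread within groups, so the 22 genes are no further evidence.

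Fold changes were compared across genes, which are not independent replicates. The DCS effects in WT and in HT had a Pearson r of -0.04 over 17256 genes, and 55 of 100 relabellings of treatment within genotype gave an r as large in size. The genotype effect without DCS and the DCS effect in HT had an r of -0.48 and a covariance of -0.0128. Both use the HT vehicle libraries, with opposite signs, and 100 permutations of the labels over the 18 libraries gave a mean r of -0.50, from -0.64 to -0.36, and a mean covariance of -0.0147. With the HT vehicle libraries split into 3 and 3, the 20 ordered splits gave a mean r of 0.04, from -0.03 to 0.13. No opposing movement beyond that of the shared libraries was detected.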

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

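All of these results came from fixed rules, and none was weighed beyond the values given. A library stood apart in its group where the gap to its nearest neighbour, divided by the range of the group, exceeded Dixon's 95% limit. Of 384 gene groups 37 did so, and of 172 list groups 11. Chance gives about 1 in 20, and genes vary together. HT vehicle replicate 6 had 9 of the gene cases and 3 of the list cases; no other library had more than 3 and 1.

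In HT vehicle replicate 6, Grin2b stood low at 14620 normalised reads against 18070 to 19880 in the other 5 libraries (gap over range 0.657), and Grin2a at 4614 against 5806 to 6300 (0.707). Without it the Grin2b log2 difference between HT vehicle and WT vehicle was 0.087. Lgi3 (0.657), Tspan2 (0.676) and Kdm5d (0.82) were also low there, and Ccn2 (0.656), Gap43 (0.714, at 9071 against 7304 to 7810), Sdhc (0.688) and Nnat (0.66) high. Its synaptic vesicle list (0.814) and voltage-gated channel list (0.844) were low and its ribosomal list (0.663) high.

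In WT vehicle, replicate 1 stood high for Adora2a (0.836, at 1557 against 1104 to 1178), Drd2 (0.627) and the striatal list (0.724). Replicate 2 was high for Shkbp1 (0.761) and Mcm3 (0.652), and replicate 3 low for the meningeal list (0.749). Replicate 4 was high for Aurkb (0.801) and low for the clock list (0.711). Replicate 6 was high for Neurod1 (0.712) and Atp5b (0.733) and low for the hypothalamic list (0.732). In WT DCS, replicate 1 was low for Col24a1 (0.758) and high for Gadd45g (0.809), Cox4i1 (0.731) and the hypothalamic list (0.764). Replicate 2 was low for Grin2a (0.867) and high for Kcne2 (0.739), and replicate 3 high for Grin3b (0.791) and low for Shisal2b (0.721). Replicate 4 was low for Lgi3 (0.913) and high for Tubb2b (0.788), and replicate 5 high for Suco (0.889). In HT vehicle, replicate 1 was high for Mcm3 (0.694), replicate 2 for Rheb (0.715) and the interferon list (0.651), replicate 3 for Pcsk1 (0.71) and Ier5 (0.74), and replicate 5 for Scml2 (0.645). In HT DCS, replicate 1 was high for Rpl12 (0.728), replicate 3 for Irak2 (0.695), and replicate 6 for Col1a2 (0.715) and Hyou1 (0.861). Replicate 4 was low for the astrocyte list (0.722). Replicate 5 was high for Rsad2 (0.643) and low for Atp5e (0.68, at 1023 against 1312 to 1448) and the cerebellar list (0.88).

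By the interaction term 7 lists were called with the preset correlation (limma camera, adjusted p from 7.69e-05 to 0.0237). With an estimated correlation the adjusted p was 0.99 for each (limma camera). Of 100 regroupings of the libraries, the real one included, 82 called as many lists, and 72 of 100 balanced on the replicate numbers did. A DCS effect that differs between the genotypes is thus not shown. The mean log2 differences, HT effect minus WT effect, were -0.268 for choroid plexus markers, -0.165 for early genes, -0.115 for myelin markers and -0.09 for heat shock genes. They were -0.078 for stress response genes, -0.073 for cerebellar markers and -0.061 for ribosomal protein genes. Without WT DCS replicate 2 the choroid plexus value was -0.163 and the early gene value -0.107. The early gene value was -0.089 without WT vehicle replicate 4, the myelin value -0.051 without HT DCS replicate 6, the stress response value -0.049 without WT DCS replicate 1 and the ribosomal value -0.034 without HT DCS replicate 5. The cerebellar value was -0.017 and its call lost without HT DCS replicate 5 (limma camera, adjusted p = 0.48); the call was also lost without WT DCS replicate 1 (adjusted p = 0.07) or WT DCS replicate 4 (adjusted p = 0.059). The heat shock call was lost without WT vehicle replicate 5, WT DCS replicate 1 or 2, HT vehicle replicate 2 or 3, or HT DCS replicate 5 or 6 (limma camera, adjusted p from 0.054 to 0.13).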

How the results depend on the processing

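The alternatives with 2 principal components, replicate numbers in 2 blocks (1 to 3, 4 to 6), the hindbrain covariate, 3 libraries left out together and permuted list means were chosen after seeing the data, and the cause of the changes was not tested. No list call held with an estimated correlation (0 lists in each of the 6 contrasts), fry (0 in each) or permutation of list means, over all libraries or within number blocks (0 in each). With the preset correlation under the other settings, 66 list calls gave 1980 values, of which 1758 kept the call, 218 lost it and 4 reversed. The 4 were the cerebellar list in HT DCS against HT vehicle without HT DCS replicate 5 (adjusted p = 0.93) and with 3 libraries left out (adjusted p = 0.94), the autism genes in HT DCS against WT DCS (adjusted p = 0.86) and the ribosomal list in HT DCS against WT vehicle (adjusted p = 0.99), both with 3 libraries left out. Of the 66 list calls, 52 were lost without at least 1 library, and in 48 the list mean difference moved by over 1.5 times or turned. Without one library at a time the adjusted p of that cerebellar list ran from 0.0041 to 0.93. Of 5755 values of named genes, 88 changed sign and 24 passed the threshold.

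Genes past the threshold, 0 in each contrast as reported (limma), became 40 in HT DCS against WT DCS and 22 in HT DCS against WT vehicle with 2 principal components. The components come from deviations within groups and leave the fold changes unchanged, so more calls are built into that setting. Lists called moved to 13 in HT DCS against HT vehicle with quantile normalisation, to 11 in WT DCS against WT vehicle with the hindbrain covariate, and, with 3 libraries left out, to 9 in HT DCS against WT DCS, 4 in WT DCS against WT vehicle and 1 in the interaction.

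With the replicate block, 11 genes passed in HT DCS against WT vehicle, among them Syt2, Scn4b and Adora2a, and 16 lists were called in WT DCS against WT vehicle; with the replicate block by description number, 2 genes passed in HT DCS against WT vehicle, Scn4b and Syt2. The numbers were not taken to pair the samples, since the 33 pairs of libraries with one number had correlations from -0.07 to 0.30 and 5 of them were over 0.1. Those of WT vehicle with WT DCS stood higher, with 3 of 5 over 0.1 and a mean of 0.104 against -0.02 for other numbers. Of the libraries, 0 of 23 correlated best with their own title number and 1 with its description number. The numbers do share a coarser structure: on the second principal component 11 of 12 libraries numbered 1 to 3 lay below 0 and 9 of 11 numbered 4 to 6 above.

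Leaving out one library at a time, genes past the threshold ran from 0 to 1 in HT DCS against WT DCS (Syt2, without HT vehicle replicate 6), HT DCS against HT vehicle (Ehd1, without HT DCS replicate 4 or HT vehicle replicate 1) and HT DCS against WT vehicle (Syt2, without HT vehicle replicate 6), and stayed at 0 in the other 3. Lists called ran from 10 to 19 in HT vehicle against WT vehicle, 6 to 17 in HT DCS against WT DCS, 4 to 13 in WT DCS against WT vehicle, 5 to 14 in HT DCS against HT vehicle, 4 to 11 in the interaction and 10 to 16 in HT DCS against WT vehicle. The correlation of the DCS effects ran from -0.076 to -0.001. Correlation of the genotype effect and the DCS effect in HT ran from -0.552 without HT vehicle replicate 6 to -0.429 without WT vehicle replicate 1. Estimated depth differed 1.47-fold between libraries, and low genes are limited by it. The count-based alternatives of the plan were not run, since the table holds normalised values.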

Other observations

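The tests of genotype over both treatments, of the relations between lists and of the myelin, striatal and Ide patterns below were chosen after the results were seen, as were the look at the replicate numbers of the regroupings and the balanced splits. The regroupings without balance were chosen before.

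Microglia markers were higher in HT vehicle than in WT vehicle in 20 of 20 genes, by 0.15 ± 0.17 (SE, log2), in 4 of 6 libraries (limma camera, adjusted p = 0.00193; adjusted p = 0.79 with an estimated correlation). That difference was 0.25 without WT vehicle replicate 2, and its call was lost without WT vehicle replicate 3 or 4 (0.09 for each; adjusted p = 0.094 and 0.089) or HT vehicle replicate 3 (0.10; adjusted p = 0.054). Over both treatments, with genotype permuted within treatment, excitatory neuron markers were higher in HT by 0.033 ± 0.012 (permutation p = 0.012) and endothelial markers by 0.065 ± 0.027 (permutation p = 0.023), and mitochondrially encoded mRNAs differed by -0.108 ± 0.044 (permutation p = 0.021), each at an adjusted p of 0.22 over 43 lists. With the myelin and striatal lists below, these are the 5 of 43 with a permutation p under 0.05. Lists of NMDA receptor subunits, postsynaptic density scaffolds, synaptic vesicle proteins, GABA and glycine synapses, astrocytes and oligodendrocyte precursors were called in none of the 6 contrasts with limma camera.

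The myelin list lay lower in HT DCS than in WT DCS by -0.204 ± 0.087 (SE, log2). A shift of level tied to the replicate numbers is argued against as the whole source by the balance of the groups. The list lay higher in numbers 1 to 3 than in 4 to 6 by 0.207 ± 0.038, but both groups hold libraries of either kind in similar shares. With these 2 blocks as a covariate the difference was -0.183 ± 0.055. Given that balance the covariate could move it little, so this fit is no separate support. The difference was -0.109 ± 0.052 within numbers 1 to 3 and -0.261 ± 0.093 within 4 to 6, and whether these differ was not tested. The first test of this used numbers 1 to 3 alone, only part of the libraries, and left it open. Less caudal tissue, which among the HT DCS libraries only replicates 5 and 6 show by hindbrain means of 5.76 and 5.97, may account for part of the difference, which was -0.145 ± 0.077 with the hindbrain mean as a covariate. The cerebellar list, also caudal, was low in replicate 5 (10.731 against 11.045 to 11.088 in the others) but not in replicate 6 (11.086). An earlier stage of maturation may too, at -0.127 ± 0.051 with the immature neuron mean. These 2 and an effect of genotype under DCS cannot be told apart, since each adjusted difference lies within its SE of the bound that would exclude the explanation. Across the 23 libraries, as deviations from the group means, the myelin list moved against the immature neuron list (Pearson r = -0.83, permutation p = 1e-05, the smallest these permutations can give, adjusted 9e-04 over the 903 pairs of lists; Spearman rho = -0.73, permutation p = 1e-04, adjusted 0.0057; r = -0.77 without WT DCS replicate 4 and HT DCS replicate 6; -0.57 and -0.75 within numbers 1 to 3 and 4 to 6). Its relation to the hindbrain list fails that adjustment (r = 0.56, permutation p = 0.006, adjusted 0.052; rho = 0.52, permutation p = 0.01, adjusted 0.088; r = 0.44 without HT DCS replicates 5 and 6; 0.48 and 0.36). Of the 903 pairs of lists, 92 had an adjusted permutation p under 0.05 by Pearson and 68 by Spearman, so a passing pair was common. Over both treatments the myelin list lay lower in HT by -0.146 ± 0.060 (permutation p = 0.025, adjusted 0.22 over 43 lists). Permuted within the blocks of numbers too, the difference was -0.133 (exact permutation p = 0.00066, adjusted 0.028). The blocks were chosen after the list was seen to differ between them, so the smaller p is not independent evidence.

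Over both treatments the striatal list lay lower in the 12 HT than in the 11 WT libraries by -0.089 ± 0.034 (SE, log2; permutation p = 0.008, adjusted 0.22 over 43 lists), with 13 of 16 members lower. Without WT vehicle replicate 1 it was -0.068 ± 0.027 (permutation p = 0.017). A genotype effect may account for it but fails the adjustment, and no gene passed over both treatments (0, limma; 1237 at an unadjusted p under 0.05; Syt2 -0.27, adjusted p = 0.0907). Less striatal tissue may too: the heterogeneity of the members' differences over its degrees of freedom was 2.97, from -0.28 for Adora2a and -0.16 for Drd2 to 0.06 for Pdyn, a spread first taken to count against lost tissue. That reading assumes that all members are equally restricted to the striatum, which no value here measures. A genotype effect and less striatal tissue therefore cannot be told apart.

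Ide, the insulin-degrading enzyme gene (GRCm38 chromosome 19, 37268743 to 37337852), was read at 3 separate levels. In WT vehicle replicates 1 to 6 it had 3093, 1966, 2930, 3012, 3125 and 2999 normalised reads. In WT DCS replicates 1 to 5 it had 1886, 2913, 2832, 2100 and 3039. In HT vehicle replicates 1 to 6 it had 2008, 2903, 1927, 3913, 4275 and 1924, and in HT DCS replicates 1 to 6 it had 3024, 1993, 2801, 3001, 3976 and 2151. Its neighbours Fgfbp3 (36917550 to 36919615) and Btaf1 (36926079 to 37012752) were at 108 and 1112 in WT vehicle replicate 2 and at 208 and 1633 in HT vehicle replicate 5. The middle and high levels had medians 1.52 and 2.01 times the low one for Ide, 1.38 and 1.84 for Fgfbp3, and 1.22 and 1.57 for Btaf1. Depth before scaling had a smaller range of 1.47-fold, but the values are scaled between libraries, so that range is no direct test. Depth is argued against by neighbours that did not step in the same libraries, Cpeb3 and March5, whose levels follow. One extra segment that runs from Fgfbp3 to Ide as on the reference is argued against as well: Cpeb3 and March5, which lie between Btaf1 and Ide, had high levels 1.01 and 1 times the low ones, and no library of the high level exceeded 1.05 times. A copy number that differs between mice, in another arrangement, may account for the steps, but while Ide and Fgfbp3 met the bounds of 10% around 1.5 and 2 times, Btaf1 did not. For reads shared with paralogs or pseudogenes elsewhere, the lowest correlation of a tested gene with Ide, -0.78, decides nothing. A partner outside the measured genes would not be seen. Fgfbp3 and Btaf1 rose with Ide across the libraries (Pearson r = 0.92 and 0.88 on log2 values), against 0.26 for Cpeb3 and -0.01 for March5. Reads shared gene by gene, each with a separate partner, would not move these 3 neighbours together, so that form is argued against. A partner that holds parts of all 3 genes and a differing copy number cannot be told apart. No biological explanation tied to the groups was tested.

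For each contrast 100 regroupings of the same libraries, the real one included, were compared. Over splits of the libraries drawn without regard to the replicate numbers, chance could not be excluded for any of the 6 contrasts. With 0 genes past the threshold, 100 of 100 regroupings gave as many by construction, and the highest other count was 2 for HT vehicle against WT vehicle, 413 for HT DCS against WT DCS, 2 for WT DCS against WT vehicle, 138 for HT DCS against HT vehicle, 330 for the interaction and 1 for HT DCS against WT vehicle. In that order, 32, 23, 84, 56, 58 and 15 regroupings gave as many genes at an unadjusted p under 0.05 (real 729, 1302, 497, 828, 756 and 1239, highest other 1932, 3218, 1727, 2700, 2984 and 2691), and 10, 43, 63, 89, 82 and 37 gave as many lists (real 16, 14, 7, 8, 7 and 14, highest other 23, 27, 24, 23, 28 and 22).

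The regrouping with 413 genes set 6 libraries numbered 1 to 3 against 5 numbered 4 to 6, so it followed the replicate numbers completely, which points to a structure of the samples tied to the numbers. The labels do not give its source. In that contrast 22 regroupings were unequal by over 0.45 in the share numbered 1 to 3. Of these, 19 gave 0 genes and the second highest count was 4, so the 413 genes rest on that regrouping alone. Regroupings unequal in the numbers, by over 0.45 in the share numbered 1 to 3, gave more genes at an unadjusted p, with medians in the order above of 1348.5, 1377.5, 892, 1237, 2182 and 1600 against 579, 786, 566, 805, 756 and 636 in those as balanced as the real groups. That structure alone need not be the source of the 138 and 330 genes past the threshold, since the other regroupings unequal by over 0.45 in those contrasts gave at most 1 and 6 genes, and 9 of 11 and 3 of 5 gave 0.

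The real groups are balanced on the numbers, so 100 splits of the libraries per contrast that keep this balance were drawn as well. In the same order, 100 of 100 gave as many genes past the threshold in each contrast (real 0, highest other 1, 1, 1, 1, 2 and 1), 13, 6, 72, 44, 25 and 3 as many at an unadjusted p (highest other 1186, 1904, 1265, 2038, 1374 and 1528), and 21, 41, 59, 82, 72 and 28 as many lists (highest other 23, 23, 20, 24, 25 and 20). Of the 18 counts 1 fell under 5%, the 1239 genes at an unadjusted p in HT DCS against WT vehicle, and the other 17 did not. Chance is not excluded by it, since these splits were chosen after seeing the data and the count was not adjusted for the 18. The counts of 0 genes past the threshold could not have fallen under 5%. With numbers 1 to 3 and 4 to 6 as a covariate, 0 genes passed in each of the 6 contrasts (limma; 878, 1414, 556, 1045, 872 and 1527 at an unadjusted p under 0.05).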
